A study of Mus musculus with 22 samples.

How the data were processed

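RNA from primary mouse embryonic fibroblasts (MEFs) was compared between wild-type embryos (WT) and embryos without Lsh (KO). Lsh is the protein of the gene Hells, a chromatin remodeller of the SNF2 family needed for normal DNA methylation. Per the labels' protocols, the cells came from the body of embryonic day 13.5 C57BL/6 embryos and were used at passage 3 to 4. The labels describe 22 samples, of which 4 RNA libraries (replicates 1 and 2 of each genotype) were used. The other 18, which are input, RNA polymerase II, H3K27me3 and H3K4me3 samples, are not analysed here. The labels call the RNA samples biological replicates and do not say whether a replicate number marks a shared litter, day or run.

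Per the labels' protocols, total RNA was treated with DNase and with RiboMinus, poly-A RNA was selected on poly-T beads, and libraries were sequenced on a Genome Analyzer IIx. The deposited values are RPKM, reads per kilobase of transcript and M (mega) mapped reads, computed by the authors for each RefSeq transcript. The submitters' processing notes name the build mm9 and the program Partek, and the deposited readme names Cufflinks. The aligner and the treatment of reads that match several places are not given in the sources used here. The rows cover chromosomes 1 to 19, so genes on X, Y and the mitochondrial genome, including the Rhox cluster and the markers of embryo sex, are not analysed here. The planned test of X-linked genes could therefore not be made.

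The replicate 1 libraries have 26886 transcript rows and the replicate 2 libraries have 21136, all of them among the former. No row of the replicate 2 libraries was at 0 in both genotypes, and the 5750 rows of the replicate 1 libraries alone reached at most 1.19 RPKM. The libraries were thus processed differently by replicate number. Of the rows, 95.3% matched a RefSeq gene table by accession, and symbols were taken as the rows give them. Gapdh was listed at 0.160, 0, 0.298 and 0.179 RPKM in WT1, WT2, KO1 and KO2, whereas Actb was at 2306, 1492, 1825 and 1228. A value of 0 therefore cannot be read as silence, and genes with near-identical copies are uncertain.

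In genes with a single exon, RPKM times length comes in whole steps of 1 read, which gives the number of mapped reads. Olfactory receptor loci gave 132.2 M reads for WT1, 176.6 M for WT2, 122.5 M for KO1 and 136.1 M for KO2. A step was called whole within 0.02 of a read, and at least 95.2% of the loci used were whole in each library.

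Transcript rows were summed per gene symbol, which left 16271 genes in all 4 libraries. The 11149 genes with at least 0.5 RPKM in at least 2 libraries were tested on log2(RPKM + 0.5), with no further scaling. Fold changes are on this scale, which understates the change of low genes. The planned design was limma 3.58.1 (lmFit, then eBayes with trend and robust variance) in R 4.3.3 with genotype as the only term. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The alternative with the replicate number as a second term was also planned. It is given beside the planned design throughout because the libraries split by number. In that fit 1 residual degree of freedom remains per gene, so its p-values rest mainly on the variance shared across genes (prior degrees of freedom 9.68). In the planned design the p-values measure the spread between the libraries of a genotype. With the replicate number as a term they measure how far the 2 KO minus WT differences within the numbers disagree. The spread between the replicate numbers does not enter them. Both concern these 4 libraries only.

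The gene lists, the designs, the rule for naming genes and most alternatives were fixed before the data were examined. A list was tested with camera (preset correlation 0.01) where at least 3 members passed the filter, which held for 25 lists. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera's test has only the residual degrees of freedom, 2 in the planned design and 1 with the replicate number as a term. It could therefore hardly pass a list here, and its outcome does not tell whether correlation accounts for a call. The lists were DNA methylation machinery, Polycomb complex subunits, H3K4 methyltransferases and demethylases, RNA polymerase II subunits, protocadherin clusters, imprinted genes, Hox clusters, developmental transcription factors, pluripotency, senescence and p53, cell cycle, interferon-stimulated, inflammatory, extracellular matrix, smooth muscle, skeletal muscle, adipocyte, neuronal, chondrocyte and osteoblast, epithelial, endothelial, blood and macrophage, replication-dependent histone, ribosomal protein and immediate early genes. The germline, hepatocyte, Rhox, mitochondrial and embryo sex lists had too few tested members. Named genes were Hells, the 15 genes per direction with the largest change among those past the threshold (filled with the smallest p where too few passed and both KO libraries lay outside the WT range), up to 4 members per list, and genes on in 1 genotype alone. The same rule was applied to the fit with the replicate number as a term after the data were seen. Other genes were chosen after their values were seen.

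On simulated values for the 11149 genes, with the replicate difference of the real libraries, the planned design recovered 0 of 100 genes changed by 1 on the log2 scale and 0 of 100 changed by 2. With the replicate number as a term 97 and 100 of the 100 were recovered, with 16 false calls. The simulation gave both genotypes the same replicate difference and took its noise from the variances of the fit with that term. It thus assumes that the numbers pair the libraries and that this fit holds. The recovery with that term is therefore partly built in and does not show that the calls in the real libraries are right. Of 200 simulated lists of genes drawn at random, camera gave a p below 0.05 for 9 without and 6 with that term. These lists could hold changed genes, and the simulated genes varied independently. The estimated correlation of the blood and macrophage list reached 0.94 in the planned design, so these rates do not carry over to lists whose members move together. Other alternatives were pseudocounts of 0.1 and 1, no filter, a mean of at least 2 RPKM, median-ratio and quantile scaling, eBayes without trend, a test against a 1.5-fold change, the transcript with the highest mean, and each library left out in turn. Tables and plots were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Coordinates are mm9, 1-based with both ends included.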

Results

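Gene expression was measured by RNA sequencing in primary MEFs of 2 genotypes, WT and KO for Lsh, with 2 libraries each. The libraries are called WT1, WT2, KO1 and KO2 after their genotype and replicate number. They held 132.2, 176.6, 122.5 and 136.1 M (mega) mapped reads, and 9284, 10058, 9176 and 10068 genes reached 1 RPKM in them.

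Hells (chromosome 19, 39005480 to 39042767, plus strand), which encodes Lsh, was at 0.865 and 1.06 RPKM in WT1 and WT2 and at 0.430 and 0.550 RPKM in KO1 and KO2. The KO level was 0.497 of the WT level for replicate 1 and 0.521 for replicate 2, so its direction followed the labels in both. The log2 change was -0.56 (SE 0.34, 2 libraries per genotype), and limma gave an adjusted p of 1.00. With the replicate number as a term the SE was 0.16 and the adjusted p 0.20, so Hells missed the threshold in both fits. Which part of the gene was deleted is not stated in the labels, and a transcript value outside the deleted part would not test the genotype.

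The libraries were more alike by replicate number than by genotype. Across genes, which are not independent replicates, Pearson's r was 0.980 between WT1 and KO1 and 0.983 between WT2 and KO2, against 0.893 between WT1 and WT2 and 0.897 between KO1 and KO2. Between the replicate numbers 5323 genes (47.7%) differed in limma with genotype and number as terms. Dlk1, an imprinted growth regulator, was at 7.10 and 3.29 RPKM in WT1 and KO1 and at 132.3 and 59.0 in WT2 and KO2. Inhba, an activin subunit, went the other way, with 124.9 and 288.6 RPKM in WT1 and KO1 and 4.79 and 8.29 in WT2 and KO2. KO minus WT differences are therefore given within each number as well as pooled.

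The comparison of KO with WT asks which transcripts differ when Lsh is missing. In the planned limma fit, with genotype as the only term, 0 of 11149 genes passed the adjusted threshold, 41 had an unadjusted p below 0.05 and the lowest adjusted p was 1.00. With the replicate number as a term 75 genes passed, 42 raised and 33 lowered in KO, and 1015 had an unadjusted p below 0.05. "Rose" and "fell" below refer to that second fit, in which every gene named with these words lay on the same side within both replicate numbers. The count is not stable: it was 3 when the transcript with the highest mean stood for each gene, and 0 with no filter on low values. With a pseudocount of 0.1, 35 of the 75 calls were kept; those of Nnat, Tecr, Col2a1, Krt7, Cxcl2, Isg15 and Pcdhb17 ended, among others.

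**Figure D1:**
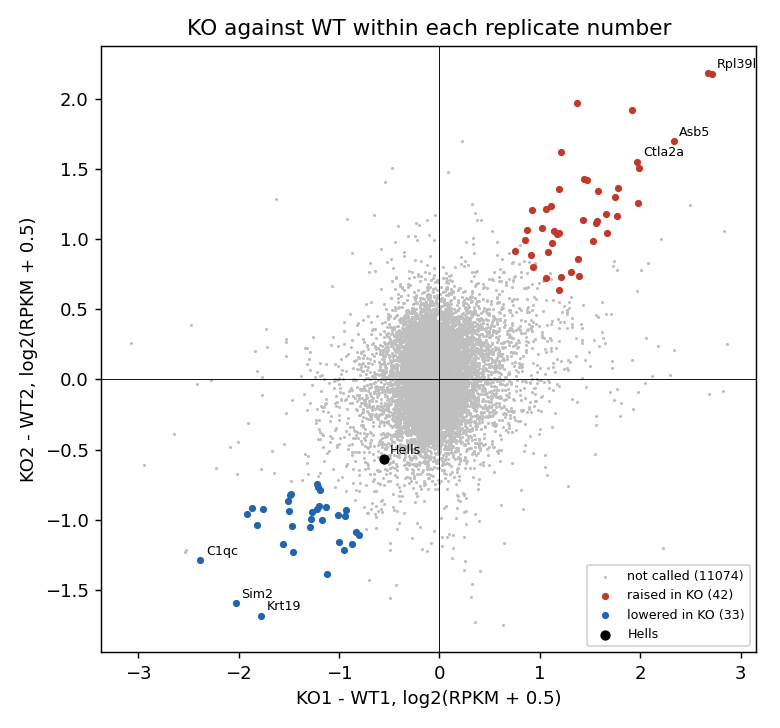
Each point is 1 of 11149 tested genes; the x axis is the KO1 minus WT1 and the y axis the KO2 minus WT2 difference in log2(RPKM + 0.5). Red and blue mark the 42 raised and 33 lowered genes of the fit with the replicate number as a term, which lie in the upper right and lower left, and the black point is Hells.

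Among the raised genes, Rpl39l (chromosome 16, 10170321 to 10175004), a copy of a ribosomal protein gene, rose from 2.20 and 2.40 RPKM in WT1 and WT2 to 17.2 and 12.6 in KO1 and KO2 (log2 change 2.44, SE 0.19, limma adjusted p 0.000353 with the replicate number as a term). Ctla2a, a cysteine protease inhibitor gene, rose from 4.90 and 5.26 to 20.6 and 16.4 RPKM (adjusted p 0.00188 in the same limma fit). Wisp2, a secreted protein of the CCN family, rose from 17.6 and 19.03 to 40.7 and 49.4 RPKM, and Tubb3, a beta tubulin best known from neurons, from 18.5 and 14.7 to 41.4 and 31.2 RPKM. Rpl39l and Ctla2a have close relatives in the genome, so reads shared with these copies leave their levels uncertain. Asb5 rose from 2.34 to 13.8 RPKM for replicate 1 and from 0.108 to 1.47 RPKM for replicate 2.

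Some raised genes were at or near 0 in WT. Mrgprx2, a receptor gene of the Mas-related family, was at 0.0116 RPKM in WT1, listed at 0 in WT2, and at 2.76 and 1.77 RPKM in KO1 and KO2. Defb41, a defensin gene, was listed at 0 in both WT libraries and was at 1.39 RPKM in each KO library. These 2 genes were at 1 RPKM or more in both KO libraries and below 0.1 in both WT libraries, and 0 genes showed the reverse. With limits of 0.5 and 0.05 RPKM the counts were 7 and 0, the others being Cyp2c55, Ipw, Klra5, Pcdha10 and Slc47a1. With limits of 2 and 0.1 RPKM they were 0 and 0, without WT2 they were 5 and 1, and without KO2 they were 11 and 3, at the first limits. Of these genes, Cyp2c55 starts at 39081509 on chromosome 19, close to Hells, which ends at 39042767. Whether the altered Hells locus itself bears on Cyp2c55 was not tested. The germline genes silenced by DNA methylation stayed low: 26 of the 29 present were below 0.5 RPKM in every library and 0 reached 1 RPKM, with the highest value for Tdrkh at 0.696 RPKM.

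Among the lowered genes, Krt19 (chromosome 11, 100002126 to 100007233), a keratin of simple epithelia, fell from 13.4 and 9.78 RPKM in WT1 and WT2 to 3.56 and 2.70 in KO1 and KO2 (log2 change -1.73, SE 0.17, limma adjusted p 0.00188 with the replicate number as a term). Sim2, a developmental transcription factor, fell from 2.57 to 0.254 RPKM for replicate 1 and from 13.3 to 4.07 for replicate 2. Tbx2, a T-box factor, fell from 1.60 to 0.264 and from 4.47 to 1.62 RPKM. The imprinted genes Nnat and Dlk1 fell, Nnat from 17.6 and 13.01 to 8.44 and 6.401 RPKM. Tecr, an enzyme of fatty acid elongation, fell from 12.1 and 18.6 to 6.59 and 8.49 RPKM, and As3mt, an arsenic methyltransferase, from 1.02 and 0.825 to 0.121 and 0.138 RPKM. Col2a1, the collagen of cartilage, fell from 3.92 and 5.42 to 0.714 and 2.63 RPKM.

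**Figure D2:**
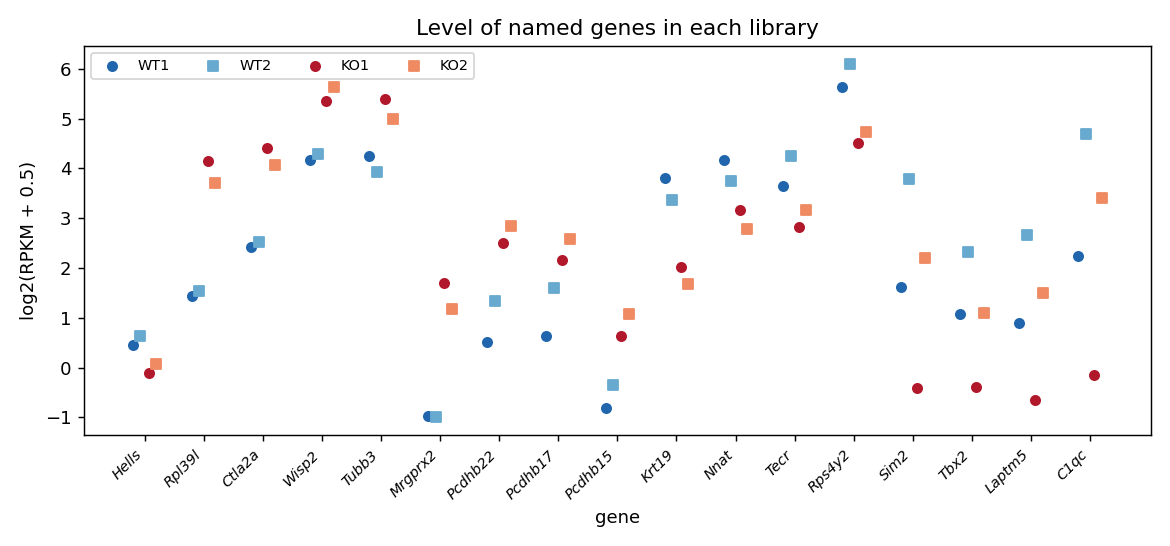
Level of 17 named genes as log2(RPKM + 0.5) on the y axis, with 1 point per library and no averaging; blue is WT, red and orange are KO, circles are replicate 1 and squares replicate 2. In Rpl39l, Ctla2a and Krt19 both KO points lie outside the WT points, whereas Sim2 and C1qc differ more between the replicate numbers.

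Among the clustered protocadherins, cell adhesion proteins of neurons encoded on chromosome 18, part of the beta cluster was higher in KO. Of the 21 beta members present, 12 were higher and 6 lower in KO within both replicate numbers. The higher ones include all 6 that passed the filter on low values, which a rise in KO helps a gene to pass, and 4 of the 6 passed the limma threshold with the replicate number as a term: Pcdhb15, Pcdhb16, Pcdhb17 and Pcdhb22, which lie between 37633200 and 37681073. Pcdhb22 rose from 0.935 and 2.03 RPKM in WT1 and WT2 (379 and 1097 reads) to 5.20 and 6.69 in KO1 and KO2 (1953 and 2793 reads). Pcdha10 of the alpha cluster rose from 0.0343 and 0.0269 to 1.08 and 0.654 RPKM. Of the 22 tested gamma members 0 passed, 5 were higher and 11 lower in KO within both numbers. For the whole list of 30, 5 rose and 0 fell over all genes tested, and 9 rose and 2 fell adjusted over the list alone. Camera gave an adjusted p of 0.00185 in the planned design and 0.000813 with the replicate number as a term, both upward. With an estimated correlation the adjusted p was 0.852 and 0.732. The list's median was 0.28 for replicate 1 and -0.11 for replicate 2. With 1 library left out it ran from -0.19 to 0.42, in fits that the difference between the replicate numbers enters.

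Blood and macrophage genes were lower in KO. Of 13 tested members, 12 were lower within both replicate numbers, and 4 fell in limma with the number as a term (11 adjusted over the list alone). C1qc, a complement subunit made by macrophages, fell from 4.1997 to 0.403 RPKM for replicate 1 and from 25.5 to 10.2 for replicate 2, and Laptm5, Fcer1g and Cd14 also fell. All 4 calls ended with a pseudocount of 0.1, and that of C1qc with median-ratio scaling as well. Among genes of blood cells outside the list, chosen after the calls were seen, Sfpi1, Fcgr3, Lcp1 and Cd52 fell too. Their calls also ended with a pseudocount of 0.1, whereas that of C5ar1, which fell as well, was kept. Cd80, Siglecg and Klra5, immune genes as well, rose. Lyz2, the macrophage lysozyme, was at 31.1 and 42.9 RPKM in WT1 and WT2 and at 3.61 and 28.0 in KO1 and KO2, and missed the threshold (adjusted p 0.796). The list's median log2 change was -1.56 for replicate 1 and -1.02 for replicate 2. Camera's adjusted p was 7.75e-09 in the planned design and 4.26e-20 with the number as a term, and 0.852 and 0.646 with an estimated correlation. The list's median ran from -2.17 to -0.054 with 1 library left out, the latter without KO1. The difference between the replicate numbers enters such fits.

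All 43 tested cell cycle genes had a log2 change below 0, and 38 were lower within both replicate numbers. The median change was -0.72 for replicate 1 and -0.21 for replicate 2. Rrm2, a ribonucleotide reductase subunit, was at 24.3 and 19.4 RPKM in WT1 and WT2 and at 11.1 and 15.7 in KO1 and KO2. Aurka, a mitotic kinase, was at 8.91 and 10.7 against 4.52 and 7.42 RPKM. In limma 0 members passed over all genes tested, and 12 fell adjusted over the list alone with the number as a term. Camera's adjusted p was 5.79e-17 in the planned design and 4.88e-19 with the number as a term, and 0.852 and 0.732 with an estimated correlation. The list's median ran from -0.93 to 0.014 with 1 library left out, in fits that the difference between the replicate numbers enters.

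Interferon-stimulated genes were higher in KO in 29 of 30 tested members, and in 23 within both replicate numbers. Isg15, a ubiquitin-like modifier, rose from 1.73 to 5.35 RPKM for replicate 1 and from 10.5 to 17.8 for replicate 2. Gbp2 was at 0.629 and 0.856 RPKM in WT1 and WT2 and at 1.92 and 1.79 in KO1 and KO2, and missed the threshold (adjusted p 0.0521, limma with the number as a term). Over all genes tested 1 member rose, and adjusted over the list alone 10 rose and 1 fell. Camera's adjusted p was 5.80e-07 in the planned design and 3.34e-11 with the number as a term, and 0.852 and 0.646 with an estimated correlation. The list's median ran from -0.24 to 0.86 with 1 library left out, in fits that the difference between the replicate numbers enters.

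Of the 35 tested Hox genes, which set position along the body axis, 21 were lower and 6 higher in KO within both replicate numbers. The lower ones were 8 of 11 Hoxa, 5 of 8 Hoxb and 6 of 8 Hoxc genes, against 2 of 8 Hoxd genes. Hoxb8 was at 8.32 and 8.75 RPKM in WT1 and WT2 and at 4.90 and 4.30 in KO1 and KO2, and Hoxa5 at 11.03 and 13.3 against 5.01 and 8.39 RPKM. No member passed over all genes tested (0 raised, 0 lowered), and adjusted over the list alone 10 fell and 2 rose in limma with the number as a term. Camera's adjusted p was 4.47e-07 in the planned design and 1.15e-06 with the number as a term, and 0.852 and 0.646 with an estimated correlation. The list's median ran from -0.69 to -0.014 with 1 library left out, in fits that the difference between the replicate numbers enters. Of 7 tested epithelial genes, 5 were lower within both numbers, Krt19 and Krt7 fell, and camera's adjusted p was 8.76e-05 and 1.15e-06 in the 2 fits (0.852 and 0.646 with an estimated correlation).

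**Figure D3:**
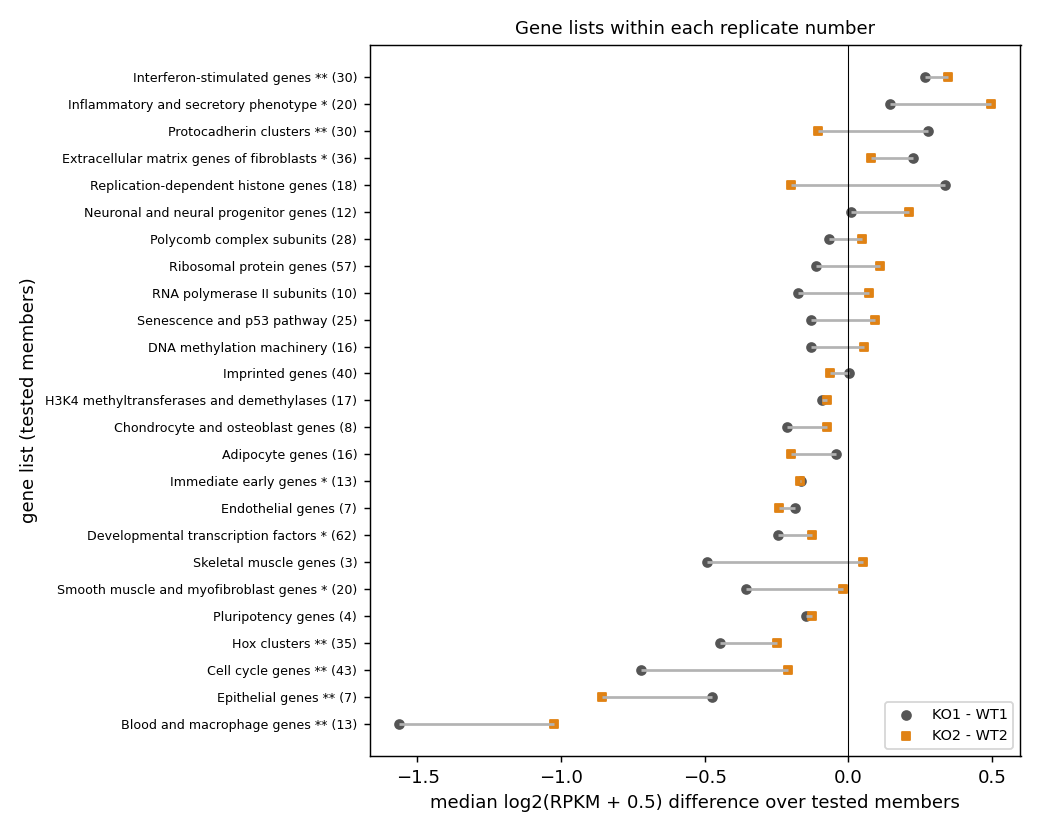
Median difference in log2(RPKM + 0.5) over the tested members of 25 gene lists (number of members in parentheses), as KO1 minus WT1 (circles) and KO2 minus WT2 (squares). A pair of asterisks marks the 6 lists past camera's threshold in the planned design and 1 asterisk those past it with the replicate number as a term alone; the blood and macrophage list lies lowest, at -1.56 and -1.02.

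With the replicate number as a term 5 more lists passed camera's threshold. Developmental transcription factors (adjusted p 0.00115, 32 of 62 lower within both numbers), smooth muscle genes (0.0209, 9 of 20) and immediate early genes (0.0449, 8 of 13) were lower, calls that were lost with an estimated correlation (adjusted p 0.646, 0.732 and 0.732). Inflammatory genes (0.000813, 10 of 20 higher within both numbers) and extracellular matrix genes (0.0158, 14 of 36) were higher, which was lost with an estimated correlation too (0.646 and 0.686). In fits without the number as a term, the median was 0.31 for smooth muscle genes without WT1 and -0.36 for inflammatory genes without WT2. The difference between the replicate numbers enters such fits, so they do not show that the direction depends on single libraries. Within replicates 1 and 2 the medians were -0.36 and -0.019 for smooth muscle genes and 0.14 and 0.50 for inflammatory genes. In the planned design camera's adjusted p for the 5 lists, in the order first named, was 0.171, 0.0755, 0.352, 0.0755 and 0.129. With an estimated correlation 0 of the 25 lists passed in either fit, with a lowest adjusted p of 0.852 and 0.646. With 2 and 1 residual degrees of freedom, that outcome does not decide whether correlation accounts for the calls. For interferon-stimulated genes with the number as a term, the estimated correlation was 0.0069, below the preset 0.01. Camera's unadjusted p nevertheless went from 4.00e-12 to 0.088. In the inflammatory list the called member, Cxcl2, a chemokine that attracts neutrophils, fell, from 2.19 and 3.93 RPKM in WT1 and WT2 to 0.445 and 1.93 in KO1 and KO2, against the direction of the list. Tnf, an inflammatory cytokine gene outside the list, fell as well, from 1.09 and 1.62 to 0.0757 and 0.531 RPKM. Its call ended with a pseudocount of 0.1.

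Genes of the DNA methylation machinery showed 0 calls among 16 tested members (camera adjusted p 0.466 and 0.336). Uhrf1, which recruits the maintenance methyltransferase, was at 3.66 and 7.64 RPKM in WT1 and WT2 and at 1.99 and 5.88 in KO1 and KO2. Dnmt1, that methyltransferase, was at 1.49 and 2.98 against 1.16 and 2.54 RPKM. Polycomb subunits (camera adjusted p 0.641 and 0.868), H3K4 methyltransferases and demethylases (0.466 and 0.550) and RNA polymerase II subunits (0.636 and 0.550) were not called either. Imprinted genes as a list were not called (0.907 and 0.332), although Nnat and Dlk1 fell.

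Across the 11149 genes, the KO minus WT difference of replicate 1 and that of replicate 2 had a Pearson r of 0.265 and a Spearman rho of 0.172, and 53.8% of genes had the same sign. These 2 differences share no library, so chance gives a correlation of 0 on average. Genes do not vary independently, so how far from 0 chance can reach cannot be told from 2 differences.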

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

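A signal was seen in rows that the comparisons do not use. Of the 5750 transcript rows of the replicate 1 libraries alone, 344 had a value above 0 in KO1 against 233 in WT1, although KO1 was sequenced to 122.5 M (mega) reads and WT1 to 132.2 M. These are 5.98% (95% exact binomial interval 5.38% to 6.63%) and 4.05% (3.56% to 4.59%) of the rows. Olfactory receptor loci, which are used in the estimate of depth, went the same way: of 989 loci, 40 (4.04%, interval 2.90% to 5.47%) had reads in KO1 against 17 (1.72%, 1.00% to 2.74%) in WT1, and 30 in KO2 against 23 in WT2. Most of these loci are among the 5750 rows, so for replicate 1 this is largely not a second observation. Loci without a row in the replicate 2 libraries were counted as 0 there. The intervals cover counting error only and compare the libraries, not the genotypes. The highest value was that of Edn2, with 0.335 RPKM in WT1 and 1.19 RPKM in KO1.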

How the results depend on the processing

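The fit with the replicate number as a block called 75 genes (42 raised, 33 lowered) where the planned design called 0. On simulated values the planned design recovered 0 of 100 genes changed by 2 on the log2 scale. Its count of 0 could therefore hardly have been otherwise and does not show that no gene changed. Without the block 0 genes were called under every alternative, each library left out included (0 to 0). The block was planned, but the labels do not say that the numbers pair the samples: the deviations of the numbers had a correlation of 0.875 across genes, and the rows of the libraries differ by number. With the block, median-ratio scaling called 105 genes (59 raised, 46 lowered; 72 of the 75 shared) and quantile normalization 187 (99 and 88; 74 shared). Alternatives chosen after seeing the data, all with the block, were a pseudocount of 0.1 (37 genes, 8 of them lowered; 35 shared) or 1 (59; 57 shared), no filter on low values (0, 0 raised and 0 lowered), a mean of at least 2 RPKM (26, 16 and 10; 26 shared, with 39 of the 75 tested), eBayes without trend (77; 68 shared), a test against a 1.5-fold change (7, 5 and 2: Rpl39l, Asb5, Ctla2a, Defb41, Mrgprx2, Krt19 and Sim2) and the transcript with the highest mean (3, 3 and 0: Rpl39l, Mrgprx2 and Defb41). The cause was not tested; the prior degrees of freedom were 4.17 with no filter and 5.43 with the highest transcript, against 9.68. No library could be left out of the fit with the block, since no residual degree of freedom would remain. Hells stayed lower, from -0.85 to -0.40, and missed the threshold under each alternative, fixed beforehand, in which it was tested; with a mean of at least 2 RPKM it was filtered out, and the alternatives added with the block were followed as counts only.

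Of 25 lists, 6 were called as planned, 11 with the block, 0 with an estimated correlation and 0 with fry, whose lowest adjusted p was 0.986, or 0.495 with the block. The 0 with an estimated correlation rests on 2 residual degrees of freedom, or 1 with the block, so it decides little. With libraries left out, 5 to 12 lists were called; the design is then unbalanced over the replicate numbers, and the lone library is assumed to vary like the others. In these fits the median changed sign for 22 of the 25 lists. Of the 11 lists called in either fit with all libraries it did for 8: protocadherin (-0.19 to 0.42), interferon-stimulated (-0.24 to 0.86), smooth muscle (-0.81 to 0.31), inflammatory (-0.36 to 0.99), cell cycle (-0.93 to 0.014), developmental transcription factor (-0.72 to 0.30), extracellular matrix (-0.32 to 0.33) and immediate early genes (-0.92 to 0.32). The median kept its sign for the Hox (-0.69 to -0.014), epithelial (-1.33 to -0.29) and blood and macrophage lists (-2.17 to -0.054). With a library left out, camera called 2 of the 11 the other way: smooth muscle genes up without WT1 and inflammatory genes down without WT2. It also called 6 lists that neither fit with all libraries called, and their medians changed sign too: senescence and p53 (-0.16 to 0.026) and replication-dependent histone genes (-0.61 to 0.60), each called up and down, and imprinted (-0.27 to 0.34), adipocyte (-0.50 to 0.32), skeletal muscle (-0.61 to 0.17) and pluripotency genes (-0.69 to 0.31), each called down once. Of 81 genes followed, the change turned sign for 8: Mmp13 (-0.15 to 2.28), Ier3 (-0.67 to 0.30), Spint2 (-1.33 to 0.23), Zfp36 (-0.9995 to 0.25), Uhrf1 (-1.22 to 0.13), Fbln5 (-0.69 to 0.061), Jun (-1.12 to 0.32) and Fcer1g (-2.97 to 0.11). Genes on in KO alone numbered 2, or 0 with limits of 2 and 0.1 RPKM, 7 with 0.5 and 0.05, and 2 to 11 with libraries left out; those on in WT alone numbered 0, or 0 to 3. The correlation of the differences within numbers was 0.265, and -0.803 for crossed pairs, where the difference between the numbers enters with opposite sign. The planned test of X-linked genes was not run, since only chromosomes 1 to 19 were covered. The pseudocount understates changes near 0.5 RPKM; depth was not shown to be the limit there, since Pcdhb15 at 0.0677 RPKM in WT1 still had 25 reads.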

Other observations

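The tests below were chosen after the result they bear on had been seen, except the test of macrophage genes outside the fixed list.

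Some imprinted genes, chosen after their values were seen, were higher in both replicate 2 libraries than in both replicate 1 libraries. H19 was at 661 and 105 RPKM in WT1 and KO1 and at 3604 and 2756 RPKM in WT2 and KO2. Igf2 was at 548 and 117 against 2239 and 1443 RPKM, Mest at 3.16 and 2.58 against 187 and 116 RPKM, and Cdkn1c at 12.2 and 20.7 against 258 and 232 RPKM.

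The lists not described so far were not called by camera in either fit. Adjusted p in the planned design and with the replicate number as a term was 0.965 and 0.754 for the senescence and p53 genes, 0.352 and 0.218 for pluripotency genes, 0.514 and 0.237 for skeletal muscle genes and 0.406 and 0.417 for adipocyte genes. It was 0.171 and 0.332 for neuronal genes, of which Tubb3 rose, 0.147 and 0.132 for chondrocyte and osteoblast genes, of which Col2a1 fell, and 0.514 and 0.336 for endothelial genes, of which Flt1 rose from 2.11 and 1.21 to 5.17 and 2.87 RPKM. It was 0.638 and 0.445 for replication-dependent histones and 0.471 and 0.574 for ribosomal protein genes, of which Rpl39l rose and Rps4y2 fell. Of the 3 hepatocyte genes present, 0 reached 1 RPKM in any library.

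Fewer macrophages in the KO cultures are a candidate explanation of the lower blood and macrophage genes. Of 35 macrophage-lineage genes outside the fixed lists with a mean of at least 0.2 RPKM, 85.7% were lower in KO within both replicate numbers, with a median WT over KO ratio of 5.10 and 1.89. Among the most abundant, Mpeg1 was at 2.37 and 7.51 RPKM in WT1 and WT2 and 0.207 and 4.54 in KO1 and KO2, while Rgs10 (3.20 and 6.64 against 3.46 and 5.81) moved less and Cd53 was higher in KO (0.408 and 1.80 against 4.08 and 2.17); how many of the 35 fibroblasts also express was not tested. A shift of all genes at such levels is argued against, since the 2.5th percentile of 10000 random lists matched on expression was -0.16 and the list's median log2 change was -1.34. Lower transcription of these genes within macrophages in the absence of Lsh stays open. The summed RPKM of the fixed list was 61.1 in WT1, 180.2 in WT2, 8.52 in KO1 and 87.9 in KO2. This sum was lower in KO within both replicate numbers, but higher in KO2 than in WT1. With 2 libraries per genotype, macrophage content that varies between cultures whatever their genotype cannot be told apart from an effect of the genotype.

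For the beta protocadherins, of which 12 of 21 were higher and 6 lower in KO within both replicate numbers, a move of reads between copies is argued against, because the summed RPKM of all 21 was 3.66 times as high in KO1 as in WT1 and 2.03 times as high in KO2 as in WT2. Genomic DNA in the KO RNA is argued against too: the mean gain over 989 olfactory receptor loci was at most 0.00631 of the mean gain of the beta protocadherins, although more of these loci had reads in KO1 (40) than in WT1 (17) and in KO2 (30) than in WT2 (23). Neuronal cells in the KO cultures stay open: Tubb3 rose, and the median change of the 12 tested neuronal genes, 0.0078 and 0.21 (SD 0.75 and 0.36) for replicates 1 and 2, did not lie below that of the 21 beta members (0.12 and 0.16) by more than its SD. That bound could hardly be met, since the SD exceeded the median of the beta members for both replicates, so the test decides little. The 6 beta members that passed the filter had a median log2 change of 1.21, but a rise in KO helps a gene to pass. Neuronal cells and raised transcription in the absence of Lsh thus cannot be told apart here, with 2 libraries per genotype.

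The lower Hells RPKM in KO could go with the lower values of the cell cycle genes, of which 0 passed the threshold singly. For replicate 1, 13 of 43 cell cycle genes had a lower KO over WT ratio than Hells, and for replicate 2 it was 0 of 43, the lowest being Mcm5 at 0.593 against 0.521 for Hells. A single pair of libraries does not decide this, so lower cell cycle genes and the knockout cannot be told apart as the origin of the ratio. Transcript that remains from an undeleted part of Hells could not be tested either, since the gene has 1 transcript row and values per exon were not used.

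Whether the 75 genes exceed chance cannot be decided from 4 libraries. With the replicate number as a term only 1 other split exists, which pairs WT1 with KO2, and it called 0 genes (197 at an unadjusted limma p below 0.05) and 3 lists. In that split a KO change shared by both numbers enters the residual, so its low count is partly built in. These 2 splits are too few for a share under 0.05, and the real split is the 1 that called as many as 75.

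Some genes changed in KO lie near each other. Of the 42 raised genes, 10 had another raised gene within 200 kb: Pcdhb15, Pcdhb16, Pcdhb17 and Pcdhb22, Klra5 and Klra18, P2rx3 and Rtn4rl2, and Ctla2a with a predicted gene. Of the 33 lowered genes it was 6, among them Fcgr3 with Fcer1g and Ccl3 with Ccl4. Random sets of as many tested genes gave a median of 0 and at most 4 in all but the top 2.5% of 10000 sets, so both counts exceed a draw of single genes. That draw takes no account of families in tandem, whose members may share reads or regulation, so what brings the genes together stays open.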
